A study of Oncorhynchus mykiss with 72 samples.

How the data were processed

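Gill RNA of redband trout (Oncorhynchus mykiss) was sequenced from 3 strains: Little Jacks (the desert creek), Keithly (the montane creek) and their F1 cross. Fish were held at 28 °C or 15 °C and sampled on days 1, 3, 7 and 28. This gives 24 groups of 3 libraries, 72 libraries in all. Per the labels' protocols, RNA was purified on columns, ribosomal RNA was depleted and libraries were made with a ScriptSeq kit. The deposited library table states that each library holds RNA pooled from 3 fish samples of a shared rearing tank. The p-values below therefore measure the spread between such pools.

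Per the submitters' processing notes, CASAVA 1.8, Bowtie and edgeR were used, the last pair without a version. The reference transcriptome, its annotation and the filters are not given in the sources used here. The authors deposited a normalised signal per feature, a read count divided by an effective library size, in a separate table for each strain. The sample descriptions call these values CPM, but column sums ran from 0.819 to 1.77 M (M, mega), so the divisor was not the column total. The authors' library table gives other quantities as well, the quality reads (M) and the reads matched to the transcriptome (M), and the matched percent, per the labels of its columns. Each column was tied to its strain, temperature and day through its name. The descriptions of the 3 F1 cross samples at 28 °C on day 1 name the Little Jacks table, whereas the columns named for that group stand in the table of the F1 cross. The column names were followed, so that group rests on them alone. The S number of a column matched no sample label and served only as a replicate name.

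The values of each column were whole multiples of its smallest step, so reads could be recovered by division. In every library, 100% of values came out whole within 0.01. Recovered reads per library ranged from 0.276 to 19.9 M, with a median of 6.43 M, and 3 libraries held fewer than 1 M. A count of 3 reads, taken as the limit below which no fold is read, corresponded to 0.132 to 9.24 deposited units, and that limit covers counting error only. The 3 tables held values for 24343 features in Little Jacks, 24011 in the F1 cross and 24174 in Keithly, and 23234 features were in all 3.

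Before the data were examined, the main test was fixed as limma with a trended prior on log2(value + 0.5), with 1 mean per group and all 24 libraries of a strain in the fit. Features needed a value of 1 in at least 3 libraries, a filter that removed none. Calls are at a Benjamini-Hochberg adjusted p under 0.05, two-sided. Fold changes are on the log2(value + 0.5) scale and understate changes of low features. Differences between strains were tested as differences of within-strain differences over all 72 libraries, because the tables were normalised separately. edgeR's quasi-likelihood test on the recovered reads was added after seeing the data. It called 8456 features for the averaged heat effect in Little Jacks, 7089 in the F1 cross and 7166 in Keithly.

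The feature identifiers carry no gene names, and 0 of 25137 matched the reference table of gene names. The 34 gene lists fixed before the data were examined (chaperones, proteasome, ion transport, immune and cell type markers and others) had 0 matched members, so none could be tested. The rule for named features asked for the largest averaged heat effects among called features with a mean of at least 5 and the same sign on all 4 days, and allowed identifiers without a name only for 2 higher and 2 lower features in all. These were ranked by the mean effect over the 3 strains among features eligible in all of them, a choice made after seeing the data. The parts of the rule on gene lists, on differences between strains and on the change over time therefore named no feature. The 9 ribosomal RNA features are the only ones named by the files.

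Several further steps were chosen after seeing the data. Recovered reads of the 3 tables were joined, scaled with TMM factors and tested with limma for strain levels at each temperature, with the day as a covariate. An earlier edgeR version of that test had been seen and was replaced because it ran too long. Features that rose or fell most in the F1 cross were chosen in its libraries and then measured in the parental strains. The position of the F1 cross between the parents was first taken over features at least 4-fold different and then also at 2-fold, because few passed. Libraries were ordered by the first component of within-group residuals over 16763 features, and 7 lay beyond its largest gap.

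The averaged and day 1 heat effects, Little Jacks minus Keithly averaged and on day 1, and the F1 cross against the parental mean in level at 15 °C were tested on simulated data with 100 features changed by 2-fold and 100 by 4-fold. For the averaged heat effect, limma recovered 66% and 94% of these in Little Jacks (24343 features), 56% and 98% in the F1 cross (24011) and 59% and 92% in Keithly (24174). At day 1 it recovered 8% and 55% in Little Jacks, 8% and 57% in the F1 cross, and 13% and 54% in Keithly. For the Little Jacks minus Keithly difference (23234 features) it recovered 40% and 87% averaged over days and 5% and 36% at day 1. For strain levels at 15 °C it recovered 72% and 97%. edgeR on the averaged heat effect recovered 67% and 97% in Little Jacks, 65% and 97% in the F1 cross, and 65% and 96% in Keithly. Of the simulated calls, 0% to 7.35% were false. The simulation changed far fewer features than the 12.5% to 15.4% called on day 1 in the data. It also drew each feature independently, without the deviation shared by the 7 libraries. Recovery in the data may therefore differ. The other comparisons were not simulated. Replicate pairs differed by more than sampling noise, with a chi-square per degree of freedom of at least 5.03 over 72 pairs.

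Single values per library were compared by permutation tests with 1e+05 resamples, two-sided. Alternatives covered the pseudocount, the filter, the scaling, the variance trend, the libraries in the fit and each library left out. Versions were R 4.3.3, limma 3.58.1 and edgeR 4.0.16, with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 for figures.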

Results

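The series compared gill transcripts of a desert strain (Little Jacks), a montane strain (Keithly) and their F1 cross at 28 °C and at 15 °C, the control temperature, on days 1, 3, 7 and 28. Each of the 24 groups held 3 libraries. Quality reads ranged from 22.4 to 72.7 M per library (M, mega), and 0.731% to 42.5% of them matched the transcriptome. Recovered reads ranged from 0.276 to 19.9 M.

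The first question was what heat did within each strain. Feature g01823, which carries no gene name, had the largest mean rise over the 3 strains among features eligible in all of them. In Little Jacks its normalised value was 194900 ± 60980 (SD, n = 3) at 28 °C on day 1 against 90.3 ± 35.5 at 15 °C. The F1 cross had 267300 ± 75560 against 93.9 ± 13.1, and Keithly 272800 ± 85520 against 93.3 ± 27.4. By day 28 it had fallen to 16450 ± 7602 in Little Jacks, 21810 ± 14060 in the F1 cross and 26490 ± 11490 in Keithly, where the 15 °C groups held 43.2 ± 3.94, 116.4 ± 80.1 and 71.2 ± 25.9. Averaged over days its log2 fold change was 9.65 (SE 0.17, limma adjusted p 4.35e-19) in Little Jacks, 9.52 (SE 0.25, 4.62e-17) in the F1 cross and 9.89 (SE 0.16, 4.25e-21) in Keithly. The fall of this effect from day 1 to day 28 passed the test in each strain, with log2 changes of -2.65, -4.01 and -2.99 and limma adjusted p of 0.00237, 0.00168 and 0.000377. Without the 7 libraries beyond the gap in the first component, these changes were -2.48, -2.72 and -2.65, so no larger fall in the F1 cross is read.

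Feature singleton_rep_c1368 was close to absent at 15 °C and rose to 5534 ± 1725 (SD, n = 3) in Little Jacks, 8113 ± 1614 in the F1 cross and 10130 ± 2481 in Keithly on day 1 of heat. On day 28 it held 26.4 ± 10.7, 66.3 ± 68.8 and 160.8 ± 141. Its 15 °C group means lay between 0.0993 and 3.35, with libraries at 0, so no fold is given for it. The largest mean falls over the strains, among features eligible in all 3, were in g03820 and g17407. Feature g03820 had 15 °C group means of 13.1 to 38.0 in Little Jacks, 41.2 to 143 in the F1 cross and 7.02 to 68.9 in Keithly, and 28 °C group means of 0.991 to 2.49, 0.357 to 0.826 and 0.311 to 2.83. Its fall passed the test at limma adjusted p of 1.61e-05, 1.96e-11 and 4.63e-07. At 28 °C it was at or under 3 reads in 3, 5 and 5 of the 12 libraries of these strains, so no fold is given for it either. On day 28 it held 2.49 ± 3.10 at 28 °C and 38.0 ± 26.2 at 15 °C in Little Jacks (SD, n = 3), and 1.59 ± 0.592 and 68.9 ± 10.3 in Keithly. Feature g17407 averaged -2.11 (SE 0.28, 1.03e-05), -3.67 (SE 0.33, 2.73e-08) and -2.70 (SE 0.29, 2.23e-07) in Little Jacks, the F1 cross and Keithly.

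**Figure D1:**
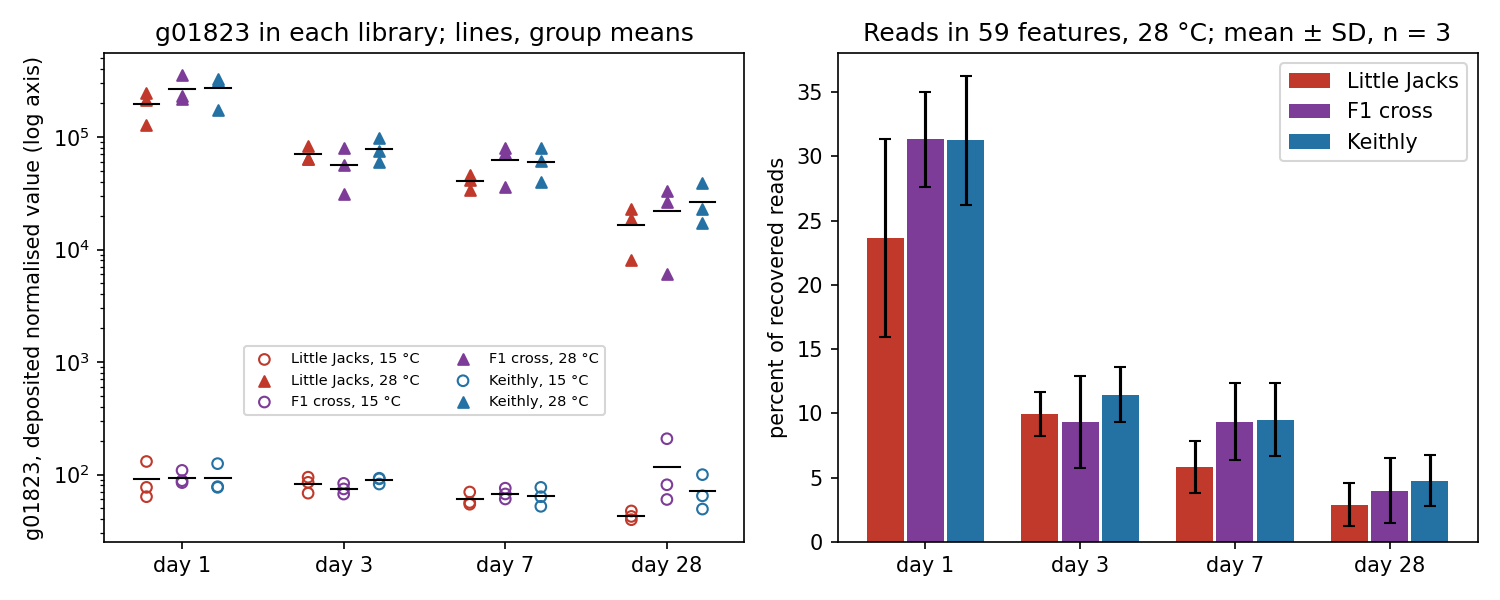
Left, normalised value of g01823 (log axis) in each library by day, strain and temperature, with group means as lines. Right, percent of recovered reads in 59 features chosen in the F1 cross, mean ± SD of 3 libraries at 28 °C, falling from 23.6% to 31.3% on day 1 to 2.90% to 4.77% on day 28.

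The 59 features that rose at least 8-fold on average in the F1 cross took 31.3% ± 3.70 of its reads (SD, n = 3) on day 1 of heat. In Little Jacks they took 23.6% ± 7.69 and in Keithly 31.2% ± 4.99. The Little Jacks mean includes replicate 1 at 14.9%, and the other 2 libraries averaged 28.0%. On day 28 the shares were 2.90% ± 1.69 in Little Jacks, 4.00% ± 2.53 in the F1 cross and 4.77% ± 1.99 in Keithly. Without 7 libraries, at both temperatures, that shared a deviation from their groups, these were 3.85%, 5.39% and 5.29% as means of 2 libraries. The 15 °C group means lay between 0.106% and 0.141%. Much of the day 1 share at 28 °C was g01823 alone, the most abundant feature in those libraries. It held a mean of 12.97% in Little Jacks, 18.62% in the F1 cross and 17.95% in Keithly. The 10 most abundant features held 19.5% ± 8.00 of reads at 28 °C and 8.64% ± 1.09 at 15 °C in Little Jacks (SD, n = 12). They held 18.2% ± 8.18 against 10.4% ± 5.68 in the F1 cross and 18.8% ± 7.83 against 9.41% ± 2.88 in Keithly. These differences passed a permutation test, with adjusted p of 0.00012, 0.0211 and 0.00112 over 12 tests, two-sided. The unadjusted p in Little Jacks, 1e-05, is the smallest these permutations can give. The 12 Little Jacks libraries at 28 °C include 3 of the 7, and these 3 held 27.2% to 29.4%. Without the 7, the shares were 16.7% ± 7.19 (SD, n = 9) against 8.64% ± 1.09 (n = 12) in Little Jacks, 18.4% ± 8.56 against 8.83% ± 1.16 (n = 11) in the F1 cross and 19.0% ± 8.19 against 8.60% ± 0.669 (n = 11) in Keithly, each at a permutation adjusted p of 0.00024 over 9 tests.

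In Little Jacks 1733 features rose and 2027 fell on day 1, 1004 and 863 on day 3, 571 and 363 on day 7, and 454 and 471 on day 28. The F1 cross had 1609 and 1388, then 1532 and 946, 595 and 552, and 618 and 735 on the same days. Keithly had 1753 and 1299, then 975 and 778, 721 and 644, and 1221 and 425. Averaged over days, 3308 rose and 3583 fell in Little Jacks, 3470 and 3065 in the F1 cross, and 3402 and 2889 in Keithly. The split into higher and lower calls depends on the scaling. With reads scaled to the column total, day 1 gave 594 higher and 10439 lower in Little Jacks, 672 and 5452 in the F1 cross and 772 and 8371 in Keithly. That scaling shifts the median of all features on day 1 by -0.81, -0.65 and -0.69 on the log2 scale, so the counts above are relative to the authors' scaling. It gave 289 and 724, 134 and 269, and 81 and 396 on the later days in Little Jacks, 694 and 869, 275 and 387, and 499 and 277 in the F1 cross, and 451 and 1641, 423 and 991, and 751 and 406 in Keithly. The averaged effect became 1006 and 10281 in Little Jacks, 1683 and 4503 in the F1 cross, and 1416 and 7784 in Keithly. The averaged split also turned with edgeR in Little Jacks (4705 and 3751), without the 7 libraries in the F1 cross (3546 and 3631) and without the 3 shallowest libraries in Keithly (3692 and 3788), so these counts give no firm majority direction.

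**Figure D2:**
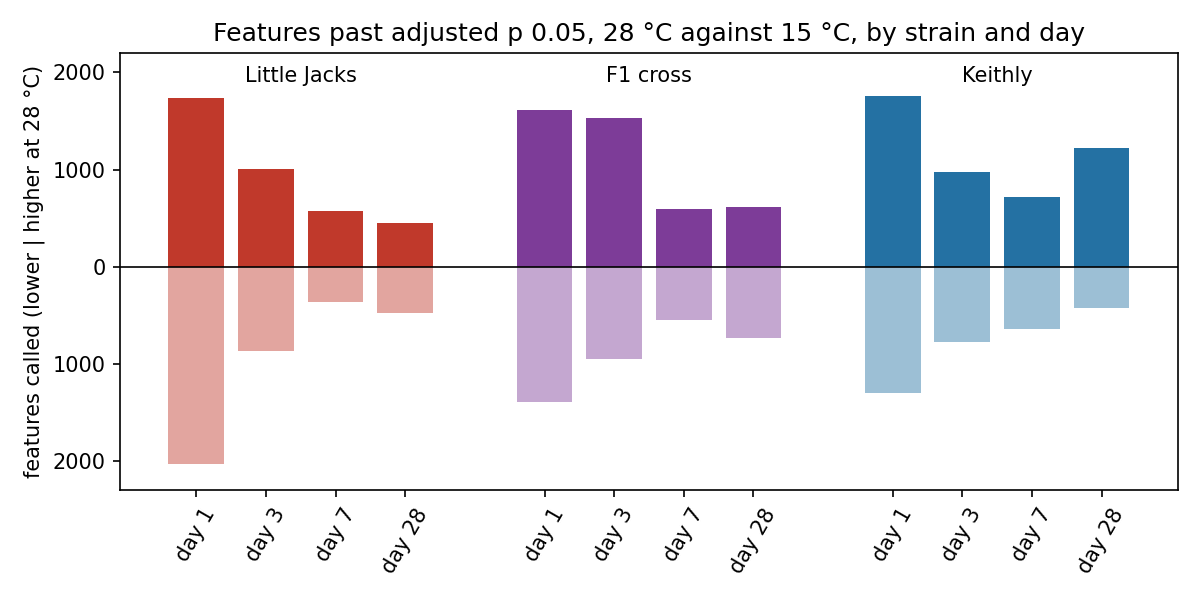
Number of features past a limma adjusted p of 0.05 at 28 °C against 15 °C, by strain and day, with higher features above the axis and lower features below it. Day 1 holds the tallest bars in each strain, with 1733 higher and 2027 lower in Little Jacks.

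Counts of single days moved with the libraries in the fit. Without the 7 libraries, the Little Jacks totals rose from 3760 to 6006 on day 1, from 1867 to 4125 on day 3, from 934 to 1905 on day 7 and from 925 to 1619 on day 28. The Keithly total for day 28 went from 1646 to 3561 without replicate 3 of its 15 °C group of that day. In the F1 cross, day 3 went from 2478 to 4234 without replicate 3 at 15 °C, and day 28 from 1353 to 2647 without replicate 2 at 28 °C. With 1 library left out, the lowest counts in Little Jacks were 1024 without replicate 2 at 28 °C on day 3, 383 without replicate 3 at 15 °C on day 7 and 458 without replicate 1 at 15 °C on day 28. In the F1 cross they were 1269 without replicate 1 at 28 °C on day 3, 462 without replicate 3 at 28 °C on day 7 and 673 without replicate 1 at 28 °C on day 28. In Keithly they were 1046 without replicate 2 at 15 °C on day 3, 743 without replicate 1 at 15 °C on day 7 and 798 without replicate 2 at 28 °C on day 28. A fit on only the 6 libraries of a day gave 1707 on day 1, 157 on day 7 and 52 on day 28 in Little Jacks, 946 on day 3 and 32 on day 28 in the F1 cross, and 94 on day 28 in Keithly, but 3424 on day 3 in Little Jacks and 4856 and 1832 on days 1 and 7 in the F1 cross and 4958 on day 1 in Keithly.

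The 9 ribosomal RNA features count what remained after depletion. Their effects are averaged over days unless a day is named. Of the mitochondrial ones, rRNA_12S_2 fell by 0.53 (log2, SE 0.15, limma adjusted p 0.00959) and rRNA_16S_1 by 0.62 (SE 0.18, 0.0141) in Little Jacks. Column-total scaling gave -0.97 (0.00123) and -1.06 (0.000424) there and also called rRNA_12S_1, rRNA_16S_2, rRNA_16S_3 and rRNA_28S_1, at -0.97, -0.94, -0.96 and -0.84. Without the 7 libraries the first pair had -0.38 (0.00727) and -0.51 (0.00467), and rRNA_12S_1 and rRNA_16S_3 were called as well. rRNA_12S_3 had -0.41 (0.0409) in Little Jacks, a call lost in 16 of the 36 alternatives for that strain, where the adjusted p ran from 0.00105 to 0.0807. In the F1 cross rRNA_16S_1 rose by 0.66 (SE 0.19, 0.0128), with 0.46 (0.130) under scaling to the column total, and the nuclear rRNA_28S_1 fell by 1.25 (SE 0.24, 0.000474). The effect in Little Jacks minus that in the F1 cross was -1.28 for rRNA_16S_1 (SE 0.29, limma adjusted p 0.00159) and -0.74 for rRNA_12S_2 (SE 0.21, 0.0178). In Keithly the limma adjusted p of the 9 averaged effects ran from 0.467 to 0.975, while column-total scaling called rRNA_12S_2 at -0.43 (0.0372) and rRNA_12S_3 at -0.39 (0.00872). On single days Keithly had calls for rRNA_18S_1 on day 1, at 2.15 (0.0499), and rRNA_28S_1 on day 28, at -1.64 (0.0414). The F1 cross had a call for rRNA_28S_1 on day 3, at -1.83 (limma adjusted p 0.0187). Mitochondrial ribosomal reads made up 0.213% ± 0.0724 at 28 °C and 0.397% ± 0.0645 at 15 °C in Little Jacks (SD, n = 12, permutation adjusted p 0.00024). The 3 Little Jacks libraries among the 7 had the lowest values of that strain, 0.0975% to 0.132%, and without them the shares were 0.245% ± 0.0506 (n = 9) and 0.397% ± 0.0645 (permutation adjusted p 0.00027). Keithly had 0.237% ± 0.0488 and 0.330% ± 0.121 (0.0211, and 0.0489 without the 7 libraries), and the F1 cross 0.262% ± 0.0534 and 0.270% ± 0.0992 (0.836). As shares of all recovered reads, these values also fall when other features take more reads at 28 °C. On the authors' scaling no averaged mitochondrial effect was called in Keithly. Nuclear ribosomal reads were 0.235% ± 0.126 against 0.617% ± 0.323 in the F1 cross (permutation adjusted p 0.00411), with 0.200 in Little Jacks and 0.195 in Keithly. The matched percent of reads also differed with temperature in the F1 cross, 30.0% ± 12.2 against 17.8% ± 8.45 (permutation adjusted p 0.0110), with 0.712 in Little Jacks and 0.195 in Keithly.

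The strains shared much of the response. Of 23234 features in all tables, 1439 rose in all 3 strains averaged over days, where independent lists would share 68.0, and 914 fell in all 3, where 54.1 would be shared. On day 1 the counts were 928 (8.57 by independent lists) and 430 (6.50). Fold changes averaged over days correlated across features at Pearson's r of 0.629 between Little Jacks and Keithly, 0.455 between Little Jacks and the F1 cross, and 0.729 between Keithly and the F1 cross, where features are not independent replicates. By day, these were 0.664, 0.587 and 0.786 on day 1, 0.572, 0.421 and 0.492 on day 3, 0.357, 0.334 and 0.607 on day 7, and 0.222, 0.0715 and 0.345 on day 28. Day 28 holds 5 of the 7 libraries and 2 of the 3 with under 1 M reads. Without the 7 its values were 0.382, 0.343 and 0.242, without the 3 they were 0.253, 0.162 and 0.401, and without both 0.540, 0.256 and 0.206. Each strain had its own 15 °C libraries.

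Features were chosen in the F1 cross and measured in both parental strains, where the medians of the sets had the sign of the F1 cross on all 4 days. Choosing a set by its effect on day 1 favours a fall with time, so sets chosen on day 28 were measured as well. The 539 raised at least 4-fold on day 1 in the F1 cross had median log2 fold changes of 2.37, 1.12, 0.97 and 0.68 on days 1, 3, 7 and 28 in Little Jacks. In Keithly they had 2.60, 1.29, 1.08 and 1.00. The 984 lowered at least 2-fold had -0.89, -0.38, -0.24 and -0.18 in Little Jacks and -1.02, -0.49, -0.47 and -0.08 in Keithly. The 59 features above had 5.29, 3.22, 2.77 and 2.07 in Little Jacks and 5.51, 3.40, 3.54 and 2.97 in Keithly. The 398 features raised at least 2-fold on day 28 in the F1 cross had 0.50, 0.66, 0.53 and 0.64 in Little Jacks and 0.71, 0.83, 1.01 and 1.01 in Keithly, so these medians were not smaller on day 28 than on day 1. The 554 lowered at least 2-fold on day 28 had medians on days 1 and 28 of -0.32 and -0.26 in Little Jacks and -0.57 and -0.02 in Keithly, where 52.0% were lower on day 28.

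**Figure D3:**
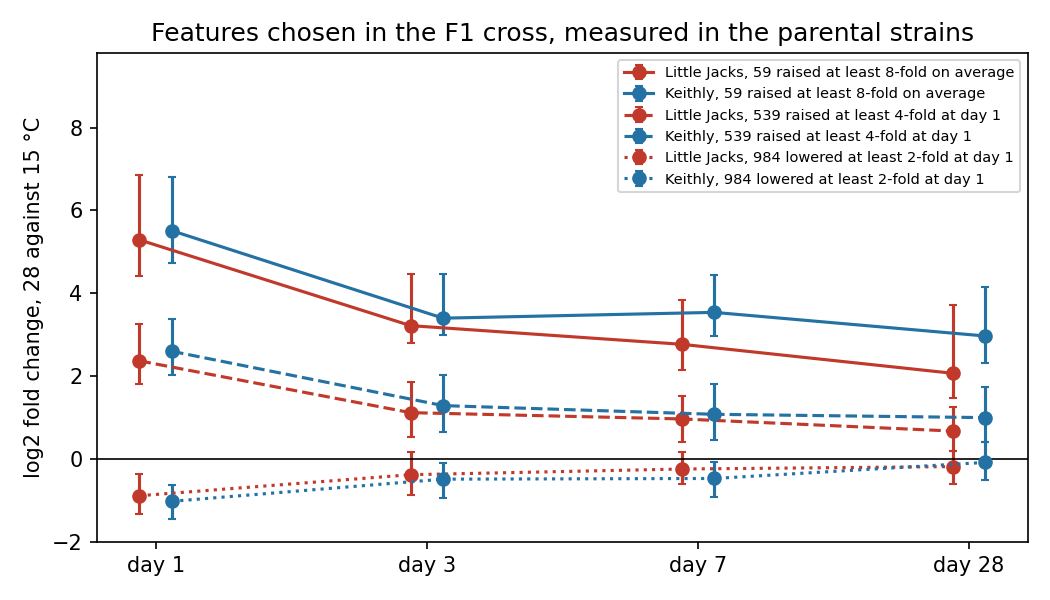
Median log2 fold change at 28 °C against 15 °C, by day, of 3 sets of features chosen in the F1 cross by their effect on day 1 or averaged over days and measured in Little Jacks and Keithly, with bars for the quartiles over features. The 59 features fall from 5.29 to 2.07 in Little Jacks and from 5.51 to 2.97 in Keithly.

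The change of the heat effect from day 1 to day 28 was tested directly. It passed for 456 features upward and 703 downward in Little Jacks, 284 and 577 in the F1 cross, and 506 and 568 in Keithly. The heat effects of g01823 and singleton_rep_c1368 were smaller on day 28 in each strain, the second at limma adjusted p of 1.31e-05, 0.000276 and 0.000179 in Little Jacks, the F1 cross and Keithly. The fall of g17407 was instead deeper on day 28 in Little Jacks, by a log2 change of -2.80 (SE 0.79, 0.0446), and in Keithly, by -2.88 (SE 0.81, 0.0432). Without the 7 libraries the Little Jacks change was -2.46 (0.0533). In the F1 cross the change of -1.49 (SE 0.94, 0.541) did not pass. The fall was not steady over days. On day 1 its limma adjusted p was 0.224, 0.000295 and 0.0967 in Little Jacks, the F1 cross and Keithly, and on day 7 it was 0.629, 0.169 and 0.0253. At 28 °C 1 of 12 libraries was at or under 3 reads in Little Jacks and in the F1 cross. The change of g03820 did not pass in any strain (0.797, 0.564 and 0.453). Among ribosomal RNA features 1 passed, rRNA_18S_1 in Keithly at -3.75 (SE 1.00, 0.0331). Column-total scaling turned the splits to 446 and 148, 2410 and 206, and 4534 and 302. The Little Jacks split was 1236 and 1263 without the 7 libraries and 1045 and 1282 with the first component's score of each library as covariate, so no majority direction is read. As background, day 28 against day 1 at 15 °C called 166 higher and 34 lower in Little Jacks, 3 and 1 in the F1 cross and 109 and 91 in Keithly, the last 82 and 171 under column-total scaling and 141 and 275 without the 7 libraries. The Little Jacks count of 200 became 85 without replicate 1 of its day 28 group and 417 higher and 235 lower without the 7 libraries, and 5 of its 6 libraries moved it over 1.5 times. The Keithly count of 200 became 2591 without replicate 3 of its day 28 group.

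The next question was whether the desert and montane strains differed in their response. Averaged over days, 208 features responded more positively in Little Jacks than in Keithly and 311 less so. edgeR turned that split, with 798 and 419, so the counts give no majority direction. g01823 differed by -0.23 (log2, SE 0.30, limma adjusted p 0.742). The 59 features as a set rose by a mean of 4.00 in Little Jacks and 4.51 in Keithly, a difference of -0.51 (log2, permutation p 0.00408, adjusted 0.0122 over 3 sets), and 50 of the 59 were smaller in Little Jacks. On days 1, 3, 7 and 28 the difference was -0.242, -0.302, -0.785 and -0.691. The 59 were chosen in the F1 cross, whose averaged fold changes correlated at 0.729 with Keithly and 0.455 with Little Jacks. That choice may favour features that rose more in Keithly. The 539 differed by -0.22 (permutation adjusted p 0.0279) and the 984 by 0.14 (0.0536). By day, limma called 1 higher and 1 lower on day 1, 18 and 3 on day 3, 9 and 11 on day 7, and 0 and 8 on day 28, with 1295, 1321, 2010 and 2913 features at an unadjusted p under 0.05 and 16, 25, 41 and 1 called by edgeR. Other scalings gave 1 and 2 on day 1 (median of ratios) and 14 and 0 on day 3 (column total). These counts moved with single libraries. Day 3 fell to 5 without replicate 1 of Little Jacks at 28 °C, and 10 of 12 libraries moved it over 1.5 times. Day 7 went from 20 to 4 without replicate 1 of Keithly at 15 °C and to 48 without replicate 3 of Keithly at 28 °C, and 8 of 12 moved it that far. Day 28 went from 8 to 863 without replicate 3 of Keithly at 15 °C and to 1 without replicate 1 of Little Jacks at 15 °C. Without the 7 libraries the days gave 16, 51, 46 and 14. On simulated data a 4-fold difference on day 1 was recovered for 36% of features.

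The heat effect of the F1 cross was compared with those of its parental strains. Against the mean of the parents, 895 features responded more positively and 1009 less so. g17407 differed by -1.26 (log2, SE 0.39, limma adjusted p 0.0326), rRNA_16S_1 by 0.97 (SE 0.25, 0.00767) and rRNA_28S_1 by -1.03 (SE 0.34, 0.0493). In Little Jacks, the F1 cross and Keithly, g17407 had 28 °C group means of 2.66 to 21.5, 1.89 to 36.8 and 2.55 to 52.1. Its 15 °C group means were 19.9 to 47.1, 80.6 to 120 and 20.0 to 172. The 15 °C level of the F1 cross may thus carry part of its difference. Little Jacks minus the F1 cross called 1098 higher and 1211 lower, and Keithly minus the F1 cross 679 and 331. The split of Little Jacks minus the F1 cross turned with edgeR (2688 and 1322) and without the 7 libraries (1446 and 1046). Column-total scaling gave 1344 and 495 for the F1 cross against the parents, 590 and 2059 for Little Jacks minus the F1 cross, and 280 and 267 for Keithly minus the F1 cross. Without the 7 libraries, 2502 features were called against the parents, and 89.1% of the main calls were among them.

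Levels of the strains were compared on recovered reads joined over the separately normalised tables. At 15 °C the parental strains differed in 44 features, while the F1 cross differed from Little Jacks in 2128, from Keithly in 1552 and from the parental mean in 2478 (1206 higher and 1272 lower). Without the 7 libraries the last split turned to 1367 and 1235, so it gives no majority direction. At 28 °C the parental strains differed in 406 features, the F1 cross from Little Jacks in 119, from Keithly in 16 and from the parental mean in 18. Among 1904 features whose heat effect in the F1 cross departed from the parental mean, 1502 differed in level at 15 °C and 18 at 28 °C, and for 1703 the level difference was larger at 15 °C. The labels give no batch for these libraries. The 15 °C difference between the parents became 17 without replicate 1 of Keithly on day 1 and 78 without replicate 1 on day 28, and 14 of 36 libraries moved it over 1.5 times. At 28 °C the parental count became 268 without replicate 1 of Keithly on day 28. The F1 cross against Keithly became 3 without replicate 1 of the F1 cross on day 3, and against the parental mean 5 without its replicate 3 on day 28, and 12 and 11 of 36 libraries moved these over 1.5 times. Without the 7 libraries the 28 °C counts of the F1 cross were 193, 28 and 40 in the order above.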

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

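Tests on the 7 libraries, the 59 features and the strain levels were chosen after the results were seen, as were all the explanations weighed except the shallow libraries, the single sampling day, the scaling and the splits of the samples.

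Each entry here is a difference of effects between groups, found by a test of the difference itself. The change of the heat effect from day 1 to day 28 passed for 1159 features in Little Jacks, 861 in the F1 cross and 1074 in Keithly. In 100 drawn splits the real count was the highest in Little Jacks, but only narrowly (highest other 1118). It was 1114 with pseudocount 0.1, 1066 without trend and 799 without replicate 2 at 15 °C on day 1. In the F1 cross 9 splits were as high (highest other 2522) and in Keithly 5 (highest other 2479). These splits exchanged the temperatures within each day separately. A draw that swaps them mostly on 1 day turns a heat effect shared by both days into a change. The splits therefore cannot decide on chance or on a structure of the samples, and chance is not excluded in any strain. Without replicate 3 of Keithly at 15 °C on day 28 its count was 1723.

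Little Jacks and Keithly differed in the averaged heat effect of 519 features, Little Jacks and the F1 cross in 2309, and Keithly and the F1 cross in 1010. The F1 cross departed from the parental mean in 1904. In 100 drawn splits the real count was the only 1 as high in each, and the highest others were 1, 6, 1 and 0. This argues against chance, at the lowest share 100 splits can give. By day, Little Jacks minus Keithly gave 21 features on day 3 (highest other 0) and 20 on day 7 (1), each the only 1 of 100 splits as high. With limma 1321 features on day 3 and 2010 on day 7 had an unadjusted p under 0.05, where 1162 would by chance. The excess on day 3 is close to that on day 1 (1295). The splits argue against chance on both days, more weakly on day 3. They do not exclude it, since no allowance was made for the number of results tested by splits. The sizes are not firm, since leaving out 1 library gave 5 to 16 on day 3 and 4 to 48 on day 7, and leaving out the 7 libraries below gave 51 and 46. On day 1 it gave 2, also the only 1 of 100 as high (highest other 0). That count was 0 with pseudocount 2, with column-total scaling and without replicate 2 or 3 of Little Jacks at 15 °C, and 16 without the 7 libraries and with edgeR. With limma 1295 features had an unadjusted p under 0.05 where 1162 would by chance, so no difference is read from it. On day 28 it gave 8, and 4 of 100 splits, the real one included, were as high. The highest other, 1040, points to a structure of the samples. The count was 1 with edgeR, 2 without the 3 shallowest libraries, 1 without replicate 1 of Little Jacks or of Keithly at 15 °C and 863 without replicate 3 of Keithly at 15 °C, so although that share is under 0.05 no difference is read from it either.

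Among named features, the effect in Little Jacks minus that in the F1 cross was 2.47 for g03820, 1.56 for g17407, -1.04 for rRNA_12S_1, -0.74 for rRNA_12S_2, -0.87 for rRNA_12S_3, -1.28 for rRNA_16S_1 and -1.19 for rRNA_16S_2 on the log2 scale. Keithly minus the F1 cross was 2.47 for g03820. The F1 cross against the parental mean was -2.47 for g03820, -1.26 for g17407, 0.69 for rRNA_12S_3, 0.97 for rRNA_16S_1 and -1.03 for rRNA_28S_1. At 28 °C g03820 was at or under 3 reads in 5 of 12 libraries of the F1 cross, 3 of Little Jacks and 5 of Keithly, so the size of its differences depends on the pseudocount (-2.86 with 0.1 and -2.03 with 2 against the parental mean), and no difference in response is read from them.

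The first pattern is that 7 libraries shared a deviation: replicate 1 of Little Jacks at 28 °C on day 1, replicate 3 on days 7 and 28, replicate 2 of the F1 cross on day 28 at both temperatures, and on day 28 replicate 3 of Keithly at 28 °C and replicate 2 at 15 °C. A response to 28 °C is argued against because 2 of the 7 came from 15 °C. All 7 lay under the median of recovered reads (1.75 to 4.95 M against 6.43 M), which low library depth would need, yet all 3 libraries shallower than these lacked the deviation, as did 13 of similar depth, which argues against depth as the whole cause. RNA from a shared source mixed into the libraries remains a possible explanation: the 1129 features at least 8-fold up in the Little Jacks libraries had a median deviation of 3.21 in the other 4, but the 7 were picked on a shared component, so that value could hardly have come out low. A state of the fish in some tanks cannot be told apart from it, since 0 label fields give the state of a tank.

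The second pattern is that the F1 cross at 15 °C lay apart from both parental strains. The 7 libraries and the 3 with under 1 M reads are argued against, since 2602 and 3242 features were called without them, beside 2478. The deviation shared by the 7 was not itself tested as a cause. Replicate 1 of the F1 cross at 15 °C stayed in on days 1 and 28, with component scores of 39.96 and 46.05. These were the highest scores outside the 7. A deviating sampling day as the whole cause is argued against too. The 1305 features called on days 1 and 3 had a median size of 0.72 (log2). On days 7 and 28 their median signed deviation was 0.45 (0.446), with 91.6% in the same direction, though only 261 were called again in that direction. If the strain labels hold at both temperatures, strain variants against the reference would act at both, and 18 features were called at 28 °C (5 to 25 with 1 library left out, and 40 without the 7). A library batch of the F1 cross at 15 °C may equally give these values and cannot be told apart from a difference in the fish. For a batch, 0 label fields give any entry, and the mean matched percent was the lowest of the strain and temperature groups there (17.8%). Strain labels exchanged at 15 °C or at 28 °C may give these values too, and the labels were not checked independently. Of 14 features at least 2-fold different between the parents at 15 °C, 0 were called in the same direction at 28 °C.

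The third pattern is that the 59 features raised most in the F1 cross rose less in Little Jacks than in Keithly, with a difference of -0.505 (log2). Little Jacks held 3 of the 7 libraries, all at 28 °C, but without the 7 the difference was -0.437, for which no test was run. The smallest difference under the other scalings was -0.490. A weaker induction in the desert strain is one hypothesis these values could fit, found and tested on the same data, and its cause was not tested.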

How the results depend on the processing

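Alternatives added after seeing the data were edgeR, column-total scaling, the 3 shallowest libraries or the 7 libraries left out, the component score as covariate, the S number as replicate block, every alternative for strain levels and the 59 features, the pseudocounts for strain differences of single features and for their change over days, and the library shares, the correlations between strains and the change of single features without some libraries. Of 29 counts, median-of-ratios scaling kept all within 1.5 times of the main count. For the averaged heat effect, the calls of g01823, singleton_rep_c1368, g03820 and g17407 were each the same in 108 of 108 values over settings and strains. For the change from day 1 to day 28, g17407 in Little Jacks lost its call without the 7 libraries. Depth limits low features most, since 3 reads correspond to 0.132 to 9.24 deposited units by library. The alternative without a filter removed nothing and is void, and gene list tests were not run. The cause of each change below was not tested, except that fewer libraries enter some fits.

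Day 28 against day 1 at 15 °C in the F1 cross (4) became 1 with pseudocount 0.1 and with a filter of 5, 2 without trend and 2 with the replicate block. S numbers do not pair the samples (mean correlation of same-numbered libraries 0.0372, 0.0200 and -0.0234 in Little Jacks, the F1 cross and Keithly), and the block moved no other count over 1.5 times. Little Jacks minus Keithly on day 1 (2) became 0 with pseudocount 2 (limma, 1392 at an unadjusted p under 0.05). With only the strains compared, day 7 (20) became 33.

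Column-total scaling gave 11033, 1013, 403 and 477 in Little Jacks on days 1, 3, 7 and 28, 11287 averaged, 594 for the change and 94 for the control days. The F1 cross had 6124, 1563, 662 and 776, then 2616 for the change and 0 for the control days (limma, 3165 unadjusted). Keithly had 9143 on day 1 and 4836 for the change. Little Jacks minus Keithly was 251 averaged, 0 on day 1 (900 unadjusted) and 13 on day 7, and Keithly minus the F1 cross 547.

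Without the 3 shallowest libraries, the F1 cross had 1852 on day 7, Keithly 2819, 2262 and 1016 on days 3, 7 and 28 and 115 for the control days. Little Jacks minus Keithly was 835 averaged and 6, 41, 54 and 2 by day. Levels were 108 for Little Jacks minus Keithly at 15 °C and 11 for the F1 cross against the parental mean at 28 °C.

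Without the 7 libraries, Little Jacks had 6006, 4125, 1905 and 1619 by day, 2499 for the change and 652 for the control days, which were 1 in the F1 cross and 416 in Keithly. Keithly minus the F1 cross was 1651, and Little Jacks minus Keithly 16, 51, 46 and 14 by day. Levels were 104 for Little Jacks minus Keithly at 15 °C, and 193, 28 and 40 at 28 °C for Little Jacks minus the F1 cross, Keithly minus the F1 cross and the F1 cross against the parental mean.

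With the component score, Little Jacks had 3827, 2191 and 1897 on days 3, 7 and 28, 2327 for the change and 563 for the control days, the F1 control days 1, and Little Jacks minus Keithly 7, 66 and 70 on days 1, 3 and 7. With only the 6 libraries of a day, Little Jacks had 1707, 3424, 157 and 52, the F1 cross 4856, 946, 1832 and 32, and Keithly 4958 on day 1 and 94 on day 28. edgeR gave 1217 for Little Jacks minus Keithly averaged, 16, 41 and 1 on days 1, 7 and 28, and 4010 for Little Jacks minus the F1 cross.

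Other splits into higher and lower that turned, single libraries left out aside, include, for Little Jacks, 1902 and 1856 on day 1 with edgeR and 1095 and 612 with the 6 libraries, and on day 28 399 and 389 without trend, 965 and 654 without the 7 libraries, 1080 and 817 with the component score, 39 and 13 with the 6 libraries and 468 and 391 with edgeR. The Little Jacks average was 4207 and 4185 with the component score. The F1 cross had 1010 and 1078 on day 3 and 572 and 558 on day 28 with edgeR, and 21 and 11 on day 28 with the 6 libraries. Little Jacks minus the F1 cross was 1276 and 958 with the component score. Little Jacks minus Keithly on day 7 was 8 and 7 without trend, 7 and 6 with column totals, 28 and 26 without the shallowest, 27 and 19 without the 7 libraries and 45 and 25 with the component score. Levels that turned without the 7 libraries were 1088 and 1040 to 1078 and 1228 for Little Jacks minus the F1 cross at 15 °C, and 190 and 216 to 248 and 157 for Little Jacks minus Keithly at 28 °C.

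Leaving out 1 library at a time gave these ranges. In Little Jacks they were 2570 to 4012, 1024 to 1323, 383 to 856 and 458 to 867 by day, 6136 to 7120 averaged, 799 to 1647 for the change and 85 to 147 for the control days. In the F1 cross they were 2033 to 2304, 1269 to 4234, 462 to 961 and 673 to 2647, 5845 to 7160, 625 to 1004 and 1 to 6. In Keithly they were 2060 to 2635, 1046 to 1782, 743 to 1253 and 798 to 3561, 5650 to 7480, 710 to 1723 and 109 to 2591. Little Jacks minus Keithly ran from 416 to 751 averaged, and 0 to 8, 5 to 16, 4 to 48 and 1 to 863 by day, Little Jacks minus the F1 cross from 2005 to 2990, Keithly minus the F1 cross from 831 to 1253, and the F1 cross against the parents from 1657 to 2299. Levels at 15 °C ran from 17 to 78, 1760 to 2828, 1255 to 1774 and 2109 to 3124, and at 28 °C from 268 to 447, 95 to 153, 3 to 20 and 5 to 25, in the same order. The 59-feature difference ran from -0.567 to -0.424. The day 28 extremes of Keithly, its control days and Little Jacks minus Keithly (3561, 2591 and 863) all left out replicate 3 of Keithly at 15 °C on day 28, where the other 2 libraries were the shallowest of all and 1 of the 7.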

Other observations

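The tests of strain levels, the position of the F1 cross and the 7 libraries were chosen after the results were seen; the splits were planned.

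At 28 °C the F1 cross lay between its parents in 89 of 106 features that differed at least 2-fold between them, with a median position of 0.381 on a scale where 0 is Keithly and 1 is Little Jacks. At the 4-fold limit set first it lay between them in 20 of 22, with a median of 0.563. Choosing features by the parental difference in the same libraries favours a position between the parents. The position was not measured again without the 7 libraries, so no intermediate inheritance is read from it. At 15 °C it lay between them in 7 of 14 at 2-fold and 0 of 3 at 4-fold. The medians there were -0.161 and -0.526, where a value under 0 lies beyond Keithly. None of the 14 features at least 2-fold different between the parents at 15 °C was called in the same direction at 28 °C (limma). All comparisons between strains rest on the strain labels at both temperatures, which were not checked independently.

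The 1129 features chosen as at least 8-fold up in the 3 Little Jacks libraries among the 7 took 24.5% to 60.1% of recovered reads in the 7 and 2.40% to 13.7% in the other libraries, with a median of 3.53%. In the 7 groups holding those libraries, 81.2% to 88.5% of matched reads were in the deposited tables, against 88.1% to 94.2% in the other 17 groups, of which 1 lay below 88.5%.

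For the heat effect on single days and for day 28 against day 1 at 15 °C, the 6 libraries make 10 splits, too few for a share under 0.05. In Little Jacks the real counts were 3760, 1867, 934 and 925 on days 1, 3, 7 and 28 and 200 for the control days, with 0 as the highest other. The F1 cross had 2997, 2478 and 1147 on days 1, 3 and 7 (highest other 0), 1353 on day 28 (highest other 1875, so 2 of 10 splits were as high) and 4 for the control days (highest other 417, 2 of 10 as high), the last pointing to a structure of the samples. Keithly had 3052, 1753 and 1365 on days 1, 3 and 7 and 200 for the control days (highest other 0), and 1646 on day 28 (highest other 1290).

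For the averaged heat effect, the real split was the only 1 of 100 as high in each strain, 6891 in Little Jacks (highest other 814), 6535 in the F1 cross (616) and 6291 in Keithly (1958). This argues against chance, at the lowest share 100 splits can give. For the strain levels the real split was likewise the only 1 of 100 as high in each comparison. These splits exchanged the labels of all 3 strains within each day. They argue against chance as the source of all strain differences at a temperature. A difference of 1 strain adds to the spread in such splits, so they cannot decide on chance for a single pair. At 15 °C the real counts were 44 for Little Jacks minus Keithly (highest other 1) and 2128 for Little Jacks minus the F1 cross (0). Keithly minus the F1 cross had 1552 (1) and the F1 cross against the parental mean 2478 (1). At 28 °C they were 406, 119, 16 and 18, with 0 as the highest other in each, although leaving out 1 library gave 3 to 20 and 5 to 25 for the last pair.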
